A study of Arabidopsis thaliana with 9 samples.

How the data were processed

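Whole-root RNA from 9 samples, 3 replicates from each of 3 fixation tubes, was hybridized by the authors to 1-colour AraGene 1.0 ST arrays with biotin label. The deposited values are log2 expression values, which the authors made with RMA (background correction, quantile normalization and median polish). The submitters' processing notes name RMA, oligo, limma, R 4.0.0 and the build TAIR10, and other settings are not given in the sources used here. The values lie between 0.0515 and 13.8, with array medians of 2.09 to 2.15, and no detection calls were available, so the number of arrays limits the precision.

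The deposited table holds 38408 probe sets. A gene name came from the naming table for 16722 with 1 gene, while 759 named several genes and 20927 were not listed. Of the former, 16574 matched the gene table and 148 did not. All 16722 were kept and gave 16550 genes. For the 146 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays was used. The gene table belongs to another release than the build in the notes, so it served for names alone. Probe sets without a single gene name were left out of the comparisons and are described in the closing section. The gene for the transgenic 14-3-3 protein kappa had no named probe set and was not analysed here. Temperature in the tubes is not given in the sources used here.

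Each pair of tubes was compared with limma 3.58.1 in R 4.3.3, with a model of the 3 groups, empirical Bayes moderation without trend, 6 residual and 3.89 prior degrees of freedom, and Benjamini-Hochberg adjustment over the 16550 genes. A gene was called at an adjusted p under 0.05. A moderated F test compared the 3 tubes together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, with tables read by pandas 2.3.3, and statmod 1.5.0 was loaded with limma. The overlap of the flight comparisons was set beside 100 simulations of 9 arrays without change in any group, with the ground group shared. Each gene had the same spread on all 9 simulated arrays, and genes were drawn independently.

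The comparisons, tests, alternatives, 26 gene and marker lists and the rule for named genes were fixed before the data were examined. Of their 425 members 55 were measured. At least 3 members were measured for 9 of these lists, 1 or 2 for 8 and none for 9. Another 19 lists were written after the naming table was seen and before any test. They include longer lists for heat shock and hypoxia, the genes of the chloroplast genome and cytosolic ribosomal proteins. The ribosomal protein and peroxidase lists were written by locus, since the gene table lacked descriptions. The 27 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation, on ranks and with fry.

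The named genes are, for each comparison, the 6 largest called rises and the 6 largest called falls. From each list up to 2 called members with the smallest p are added, or, where none was called, at most the 1 member with the smallest p as a value. Some members that the rule names are given in the tables alone. For the lists written later only called members were named, a choice made after values were seen. AT4G21870, AT5G47600, AT4G27657, PSBY, LHB1B2 and, in first-actuated roots, PSAE-1 lie outside the rule and were named after their values were seen. The values of RCA and LHCB4.1 were also given where the rule named the other of the pair. The lists counted without each array were chosen after their results were seen.

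The alternatives were another quantile normalization, cyclic loess (fast method), filters on low levels, moderation with trend and with robust fits, array weights, the replicate number as a block, the mean over probe sets, all probe sets tested, a stricter threshold, fits to 2 groups and fits without each array in turn. The pipeline was tested on simulated data with changes added to the first-actuated against ground comparison. It recovered 16.4% of 67 genes changed by 0.5 on the log2 scale, 91.0% of 67 changed by 1 and 100% of 66 changed by 2, with 8 false calls, and made 0 calls in each comparison with no change added. The changed genes were drawn only from those above the lower quartile of gene means, 1.41, so these rates do not cover dimmer genes. The simulated noise was independent, with the same spread for a gene in every tube. Since an SD of 0 was noticed, equal values, meaning values identical in every deposited digit, were also counted. From 649 to 754 probe sets had equal values on the 3 arrays of a group, and from 512 to 882 on 3 arrays not all of 1 group.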

Results

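Transcript levels were measured in whole roots of 10-day-old Arabidopsis thaliana seedlings of the Wassilewskija background that overexpressed a GFP fusion of a 14-3-3 protein, kappa, from the 35S promoter of cauliflower mosaic virus. The seedlings were sealed in 3 fixation tubes for the second flight of an F-104 Starfighter jet. In the first-actuated tube, the fixative RNAlater was released right after the microgravity phase of the parabola, and in the last-actuated tube after about 1.5 min of level flight. The ground tube stayed with a team member on the ground and was actuated during the flight. The labels describe a climb at 4 g for roughly 30 s and about 10 s of microgravity, followed by a short hyper-g pull-up. Each tube gave 3 replicates, so 9 arrays in 3 groups of 3 were compared, and their number limits the precision. The 3 replicates of a condition were taken from the roots of 1 tube, so tube and condition cannot be told apart and the p-values measure only the spread within a tube. All levels are normalized log2 expression values, and 16550 genes could be named and tested.

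The ground arrays differed more among themselves than the flight arrays did. Pearson correlations between arrays of a group were taken across the genes tested, which are not independent replicates. They were 0.976 to 0.984 for the ground tube, 0.990 to 0.991 for the first-actuated and 0.984 to 0.989 for the last-actuated tube. On the first principal component, which held 36.4% of the variance, ground replicate 2 had a score of -5.05, against -38.6 and -24.7 for ground replicates 1 and 3. The first-actuated arrays scored between 19.8 and 21.8 and the last-actuated arrays between 0.68 and 3.54. The median level of the 63 measured chloroplast-encoded transcripts, as a deviation from each gene's mean over the 9 arrays, was 1.22, -0.0050 and 0.82 in ground replicates 1, 2 and 3. By the moderated F test of limma, 737 genes differed among the 3 tubes at a Benjamini-Hochberg adjusted p under 0.05. That count was 1216 without ground replicate 2, 425 without ground replicate 3, and 340, 344 and 327 without first-actuated replicates 1, 2 and 3.

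The first comparison asked how roots fixed right after microgravity differed from roots fixed on the ground. Heat shock transcripts rose. AT1G52560, which encodes a small heat shock protein, a chaperone that holds unfolded proteins, stood at 11.10 ± 0.024 (SD, n = 3) in the first-actuated roots and at 7.36 ± 0.15 on the ground, a 13.4-fold rise (limma, adjusted p = 9.08e-08). AT5G37670, another small heat shock gene, rose from 5.35 ± 0.088 to 8.13 ± 0.076 and AT1G53540, which encodes a cytosolic small heat shock protein, from 5.48 ± 0.34 to 7.99 ± 0.18. HSA32, a heat-induced gene needed for long-lasting acquired thermotolerance, rose 4.45-fold. All 4 measured members of the fixed heat shock list rose, by 1.03 to 2.59 on the log2 scale, and 4 rose when adjusted over the list alone. In a longer heat shock list, which includes those 4 genes, 13 of 15 measured members rose and AT4G21870 fell from 2.24 ± 0.16 to 1.55 ± 0.015, a level below the median gene mean of 2.15. The median log2 changes of the lists were 2.33 and 1.28 (camera with a preset correlation, adjusted p = 5.36e-10 and 2.22e-21), and both passed with an estimated correlation (adjusted p = 0.0141 for each).

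**Figure D1:**
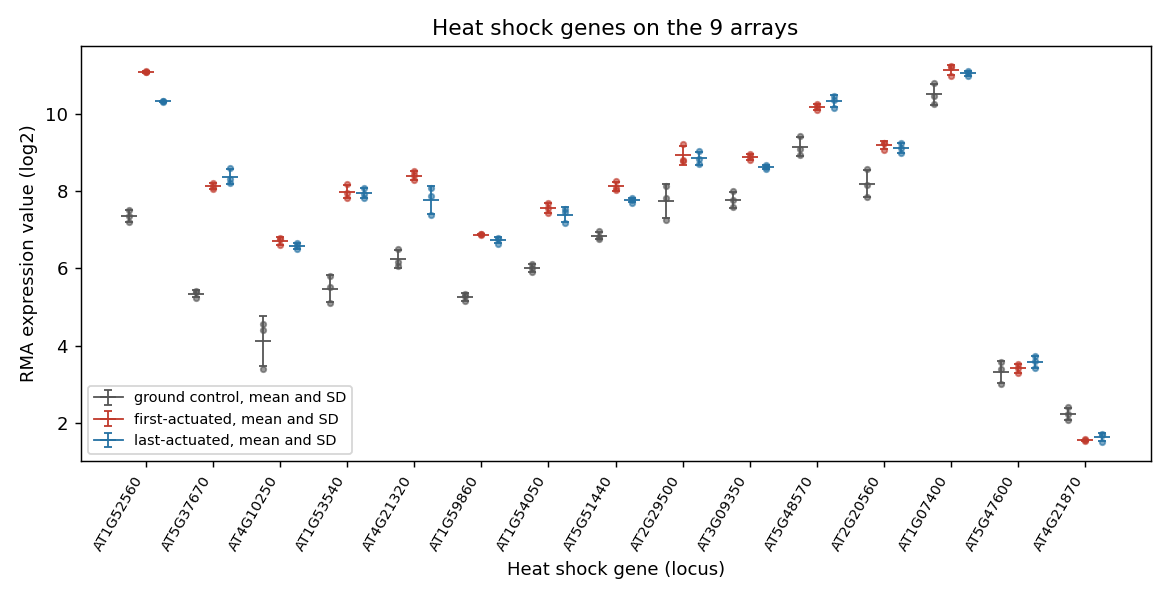
Normalized log2 expression value (vertical axis) of the 15 measured genes of the longer heat shock list (horizontal axis, by locus) on the 9 arrays; points are arrays, and horizontal and vertical bars are the mean and SD of the 3 arrays of a tube. The first- and last-actuated arrays lie above the ground arrays for 13 genes, while AT5G47600 overlaps and AT4G21870 lies lower.

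Chloroplast-encoded and cytosolic ribosomal protein transcripts had lower levels in the first-actuated roots. Of 39 measured photosynthesis genes of the chloroplast genome, 38 had a negative log2 change and 6 fell past the threshold, with a list median of -0.87 (camera, adjusted p = 3.87e-18). That call was lost with adjusted p = 0.421 with an estimated correlation. psbM, which encodes a small subunit of photosystem II, fell from 6.47 ± 0.24 to 5.45 ± 0.065 and petL, of the cytochrome b6f complex, by 0.91. The 24 other chloroplast genes had a median of -0.90 (camera, adjusted p = 2.77e-15, and adjusted p = 0.421 with an estimated correlation), and rpl14, a plastid ribosomal protein gene, was the 1 member that fell past the threshold, by 1.47. Adjusted over the list alone, 29 of the 39 and 24 of the 24 were lower. Members moved together, with estimated correlations of 0.65 and 0.85, so these counts are not of independent genes. Without ground replicate 2, 29 and 23 members of these lists fell, and without any other single array 1 and 0 did, so the calls of petL and rpl14 were lost in 8 of the 9 fits (adjusted p = 0.0634 to 0.144 and 0.0711 to 0.156). Of 15 measured nuclear photosynthesis genes, listed after RCA and LHCB4.1 had been seen and not tested as a list, 13 had a negative change and 3 fell. Their median was -0.53 (-0.32 without ground replicate 1 and -0.84 without ground replicate 2). The 3 were PSBY, of photosystem II (-0.83, limma, adjusted p = 0.0232), PSAE-1, a subunit of photosystem I (-1.30, 0.0285), and LHB1B2, a light-harvesting protein gene (-0.91, 0.0175). The count of 3 became 6 without ground replicate 2, 1 without ground replicate 1 or 3 and 0 without any 1 first-actuated array. The calls of PSBY and LHB1B2 were lost without ground replicate 1 or 3 or any 1 first-actuated array (0.0630 to 0.104 and 0.0643 to 0.0749), and that of PSAE-1 without ground replicate 3 or any 1 first-actuated array (0.0601 to 0.111). Among 129 measured cytosolic ribosomal protein genes, 116 had a negative change and 16 fell, with a median of -0.33 (camera, adjusted p = 8.12e-21, and 0.0345 with an estimated correlation). Of these, AT3G06700 fell by 0.66 and AT3G28900 by 0.86. The count of 16 became 27 without ground replicate 2, 5 without ground replicate 1 or 3, 4 without first-actuated replicate 1, 3 without first-actuated replicate 2 or 3 and 10 without last-actuated replicate 3.

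**Figure D2:**
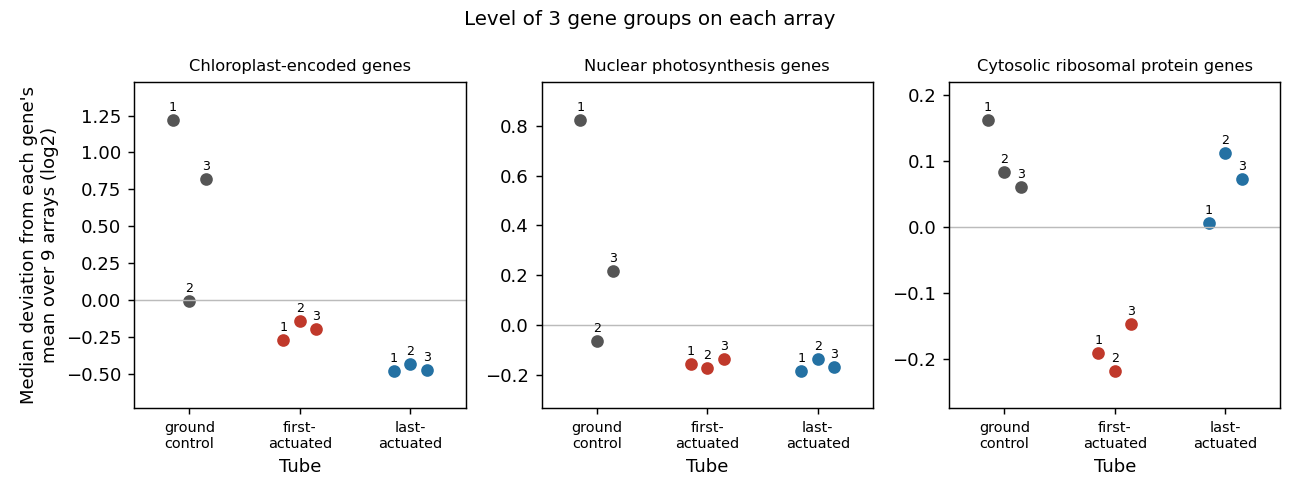
Median deviation of 3 gene groups from each gene's mean over the 9 arrays (vertical axes, log2) by tube (horizontal axes), with 1 point per array marked with its replicate number. Ground replicate 2 has a chloroplast-encoded level of -0.0050, next to 1.22 and 0.82 for the other ground arrays, and the first-actuated arrays lie lowest for the ribosomal protein genes.

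Genes tied to hormones and stress changed singly, and few of the fixed lists moved as groups. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose from 5.01 ± 0.54 to 6.64 ± 0.12 (3.09-fold, limma adjusted p = 0.00291). LBD16, a regulator of lateral root initiation, rose by 0.53. STZ, a zinc finger repressor induced by touch and many stresses, rose from 8.10 ± 0.41 to 9.04 ± 0.036. KIN1, a cold- and abscisic acid-induced gene, rose by 1.41, while LTI30, which encodes a dehydrin, fell by 0.73. AT4G27450, a hypoxia-responsive gene, fell by 0.83, and HYH, a light signalling transcription factor related to HY5, fell by 0.83. The auxin response list had a median of -0.0028, a mean of 0.29 and an upward test (camera, adjusted p = 0.324, and 0.0255 to 0.735 over its alternatives). It passed with genes above a mean level of 1.41 (median 0.53, adjusted p = 0.0255) and with genes above the median (0.0440). The list of 5 touch and calcium signalling genes had a median of 0.54 (camera, adjusted p = 0.0260, and adjusted p = 0.221 with an estimated correlation). Over all genes tested, 1 of its members rose (2 without last-actuated replicate 1 or 2, and 0 without any 1 first-actuated array), and 3 did adjusted over the list alone. Counts of members up and down adjusted over the list alone were 3 and 0 for auxin response, where over all genes 2 and 0 passed. They were 1 and 2 for hypoxia (0 and 1 over all genes), and 1 and 1 for the abscisic acid, cold and drought list (1 and 1 over all genes). For cell wall loosening they were 0 and 1 (0 and 0 over all genes by limma, with 1 member at an unadjusted p under 0.05). For the circadian clock they were 0 and 0 both ways, with 0 members at an unadjusted p under 0.05. Without ground replicate 2, the touch list had an adjusted p of 0.0831, and without first-actuated replicate 1 of 0.0805. It was also lost with genes above the median (0.0516) and on ranks (0.0795). In the longer hypoxia list 3 of 24 members rose, among them AT3G03270 by 1.15, and 2 fell (4 without ground replicate 2), with a median of -0.18 (camera, adjusted p = 0.152, and 0.0399 without ground replicate 2). The call of STZ was lost without any 1 first-actuated array (adjusted p = 0.0592 to 0.0751) and that of HYH without first-actuated replicate 3 (0.0530). That of LBD16 was lost without ground replicate 1 or 3, any 1 first-actuated array or last-actuated replicate 3 (0.0699 to 0.141), and that of LTI30 without ground replicate 2 or 3 or first-actuated replicate 1 or 3 (0.0531 to 0.113).

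In all, 776 of 16550 genes differed between first-actuated and ground roots (limma, Benjamini-Hochberg adjusted p under 0.05), of which 499 rose and 277 fell. Of these, 281 changed by at least 1 on the log2 scale. The 6 largest rises were those of AT1G44414 (from 3.68 ± 0.32 to 7.82 ± 0.029), AT1G52560, AT5G07330 (12.1-fold), AT1G72760 (from 1.56 ± 0.14 to 5.09 ± 0.20), AT1G52870 (8.70-fold) and AT2G36690 (7.85-fold). Among the 6 largest falls, AT1G13670 fell from 6.34 ± 0.62 to 3.46 ± 0.34, AT5G02580 from 3.48 ± 0.44 to 1.43 ± 0.10 and AT4G39675 from 4.06 ± 0.15 to 2.12 ± 0.14. The others were AT3G47650, which encodes BSD2, a chaperone of Rubisco assembly, AT3G16370, and AT1G32470, which encodes an H protein of the glycine cleavage system. These 3 fell from 7.34 ± 1.72 to 4.54 ± 0.37, from 4.00 ± 1.09 to 1.98 ± 0.53 and from 2.81 ± 1.06 to 1.03 ± 0.073, and their calls were lost without any 1 array other than ground replicate 2 (adjusted p = 0.0707 to 0.159, 0.0592 to 0.155 and 0.0613 to 0.121). The ground level of AT1G72760 and the first-actuated levels of AT5G02580, AT4G39675, AT3G16370 and AT1G32470 lay below the median gene mean of 2.15. No detection calls were available to place them above background, so the sizes of these changes are uncertain. Without ground replicate 2 the comparison called 1253 genes and without ground replicate 3 it called 449. It called 423, 422 and 384 without first-actuated replicates 1, 2 and 3, and 419 when only these 2 groups entered the fit. The 2 measured members of the fixed shoot marker list were not called. LHCB4.1, a light-harvesting protein gene, was at 4.82 ± 0.099 against 4.88 ± 0.013 on the ground (adjusted p = 0.834), and RCA, which encodes Rubisco activase, had a log2 change of 0.036. Of 3 root hair markers, EXPA18, an expansin gene, rose from 4.20 ± 0.25 to 5.16 ± 0.32, and 1 rose and 1 fell adjusted over the list alone. The call of EXPA18 was lost without ground replicate 1 or 3 or first-actuated replicate 1 or 3 (adjusted p = 0.0690 to 0.0861). The 4 reference genes had log2 changes of -0.0045 to 0.20 and limma called none, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05.

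The second comparison asked how roots fixed after the return to level flight differed from the ground roots. Heat shock transcripts were again higher than on the ground. AT5G37670 rose from 5.35 ± 0.088 to 8.38 ± 0.20 (SD, n = 3), an 8.17-fold rise (limma, adjusted p = 1.93e-06). AT1G52560 rose to 10.34 ± 0.014, AT1G53540 to 7.95 ± 0.13 and ATHSP22.0, which encodes a small heat shock protein of the endoplasmic reticulum, from 4.12 ± 0.64 to 6.59 ± 0.074. All 4 measured members of the fixed heat shock list rose, by 1.17 to 2.47, and 4 rose adjusted over the list alone. Their median was 1.99 (camera, adjusted p = 7.88e-12, and 0.00862 with an estimated correlation). In the longer list 12 of 15 members rose and AT4G21870 fell to 1.63 ± 0.11, with a median of 1.17 (camera, adjusted p = 5.66e-26, and 0.00862 with an estimated correlation). The longer list held 1 member that fell without ground replicate 2 and 0 without any other single array, where the call of AT4G21870 was lost (adjusted p = 0.0519 to 0.123).

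Chloroplast-encoded transcripts had lower levels than on the ground in the last-actuated roots as well. All 39 measured photosynthesis genes of the chloroplast genome had a negative log2 change and 11 fell past the threshold, with a median of -1.11 (camera, adjusted p = 2.54e-39, and adjusted p = 0.189 with an estimated correlation). psaB, which encodes a core protein of photosystem I, fell from 10.65 ± 0.31 to 9.50 ± 0.15, and petA, which encodes cytochrome f, by 0.84. Also lower were atpI of the ATP synthase, which fell by 1.58, ndhD of the NDH complex, by 1.51, psbZ, by 1.45, and psbK, by 1.34. All 24 other chloroplast genes had a negative change, with a median of -1.13 (camera, adjusted p = 3.88e-25, and adjusted p = 0.279 with an estimated correlation). Among them the 2 that passed were the plastid ribosomal protein genes rps14, which fell by 0.99, and rps4, which fell by 0.93. Adjusted over the list alone, 35 of the 39 and 23 of the 24 were lower, though members of each list moved together. Of the 15 measured nuclear photosynthesis genes, listed after RCA and LHCB4.1 had been seen, 13 had a negative change and 2 fell. Their median was -0.60 (-0.24 without ground replicate 1). The 2 were PSAE-1 (-1.53, limma, adjusted p = 0.0373), and LHB1B2 (-1.22, 0.0140). The count of 2 became 6 without ground replicate 2, 1 without ground replicate 1, any 1 first-actuated array or last-actuated replicate 2, and 0 without ground replicate 3 or last-actuated replicate 1 or 3. Without ground replicate 2, 32 and 22 members of the 2 lists fell. For the photosynthesis list, 4 fell without ground replicate 1, 3 without first-actuated replicate 1 or 2, 2 without first-actuated replicate 3, 1 without ground replicate 3 or last-actuated replicate 3 and 0 without last-actuated replicate 1 or 2. For the other chloroplast genes, 0 fell without any 1 array other than ground replicate 2. In those 8 fits the calls of atpI, ndhD, psbZ, psbK, rps14 and rps4 were lost, with adjusted p up to 0.161, 0.116, 0.135, 0.122, 0.140 and 0.136. The call of PSAE-1 was lost without any 1 array other than ground replicate 1 or 2 (0.0604 to 0.146), and that of LHB1B2 without ground replicate 1 or 3 or last-actuated replicate 1 or 3 (0.0546 to 0.0674). That of petA was lost without ground replicate 3 or any 1 last-actuated array (0.0530 to 0.0628), and that of psaB without last-actuated replicate 1 or 2 (0.0543 and 0.0562). The shoot marker RCA was at 6.42 ± 0.048 against 6.63 ± 0.20 on the ground (adjusted p = 0.524), and LHCB4.1 had a log2 change of 0.011.

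In all, 151 genes differed between last-actuated and ground roots (limma, Benjamini-Hochberg adjusted p under 0.05), of which 96 rose and 55 fell, and 59 changed by at least 1 on the log2 scale. AT1G44414 rose from 3.68 ± 0.32 to 6.51 ± 0.16 (7.09-fold) and AT1G72660 by 2.24. AT1G13670 fell by 1.92. AT5G42200 and AT3G03270, of a longer hypoxia list in which 3 of 24 measured members rose, rose by 1.52 and 0.66. The count of 3 became 1 without any 1 array other than ground replicate 1 (2) or 2 (4). That list had a median of 0.069 (camera, adjusted p = 0.327, and 2.01e-04 to 0.906 over its alternatives), and passed with genes above the median (median 0.43, adjusted p = 2.01e-04). LBD16 rose by 0.71, the 1 member of 8 in the auxin response list to pass (2 without ground replicate 2), and 1 rose adjusted over the list alone. KIN1 had a log2 change of 0.75 (adjusted p = 0.120) and was the 1 member of its list to rise adjusted over the list alone. The 14 SWEET sugar transporter genes had a median of -0.25 (camera, adjusted p = 0.0156, and adjusted p = 0.485 with an estimated correlation), and SWEET11, a sucrose exporter, fell by 0.77. That list was not called without ground replicate 3 (adjusted p = 0.0762), last-actuated replicate 2 (0.0716) or last-actuated replicate 3 (0.0687). The 129 ribosomal protein genes had a median of -0.044 (camera, adjusted p = 0.0592), and limma called none of them, with 16 at an unadjusted p under 0.05. This list passed without ground replicate 3 (adjusted p = 0.00667) and without last-actuated replicate 2 (0.00322). By limma no member of the fixed lists for touch and calcium signalling, hypoxia, cell wall loosening, the circadian clock, root hair cells or reference genes was called, over all genes or adjusted over the list alone, and 1 hypoxia gene and none of the others had an unadjusted p under 0.05. Without ground replicate 2 the comparison called 508 genes. It called 89 and 61 without ground replicates 1 and 3, and 86, 85 and 84 without first-actuated replicates 1, 2 and 3. Without last-actuated replicates 1, 2 and 3 it called 70, 58 and 53. When only these 2 groups entered the fit it called 28, of which 27 rose and 1 fell. Nearly all of the 55 falls were thus lost there, most chloroplast-encoded ones included. The call of AT1G13670 was lost without ground replicate 3 or any 1 last-actuated array (adjusted p = 0.0546 to 0.0786). Those of LBD16, AT3G03270 and SWEET11 were each lost in 7 of the 9 fits without 1 array, the exceptions being ground replicate 2 for all 3, last-actuated replicate 2 for LBD16 and ground replicate 1 for the other two (adjusted p up to 0.136, 0.117 and 0.146).

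Genes called in both comparisons mostly moved the same way. AT1G44414, AT1G52560, AT5G37670 and AT1G53540 were among the 80 genes that rose in both flight tubes, and AT1G13670 was among the 26 that fell in both. Independent lists of these sizes would share 2.89 and 0.92 genes, though lists that share the ground arrays are not independent. In 100 simulations without change in any group, where both comparisons shared the simulated ground group, 0 genes were called in both. At most 1 gene was called in either comparison there, so that 0 says little of shared calls between real changes. A single gene, AT4G27657, was called in opposite directions, and its call in last-actuated against ground roots was lost without any 1 array other than ground replicate 1 (adjusted p = 0.0548 to 0.159). Log2 changes correlated across genes, which are not independent replicates, with r = 0.643 against 0.500 in the simulations. Their covariance was 0.0630 against a simulated 0.0134, a difference of 0.0495. The simulations gave each gene the same spread in every tube. The real ground arrays varied more, with a median gene SD of 0.163, against 0.124 in first-actuated and 0.148 in last-actuated arrays. Both simulated values may therefore be too low for these arrays, and the excess too large. The 3 ground arrays cannot be split with at least 2 in each part, so part of the excess may come from the shared controls. The 106 genes called the same way became 416 without ground replicate 2. They were 69 and 50 without ground replicates 1 and 3, 66, 65 and 63 without first-actuated replicates 1, 2 and 3, and 56, 44 and 40 without last-actuated replicates 1, 2 and 3.

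**Figure D3:**
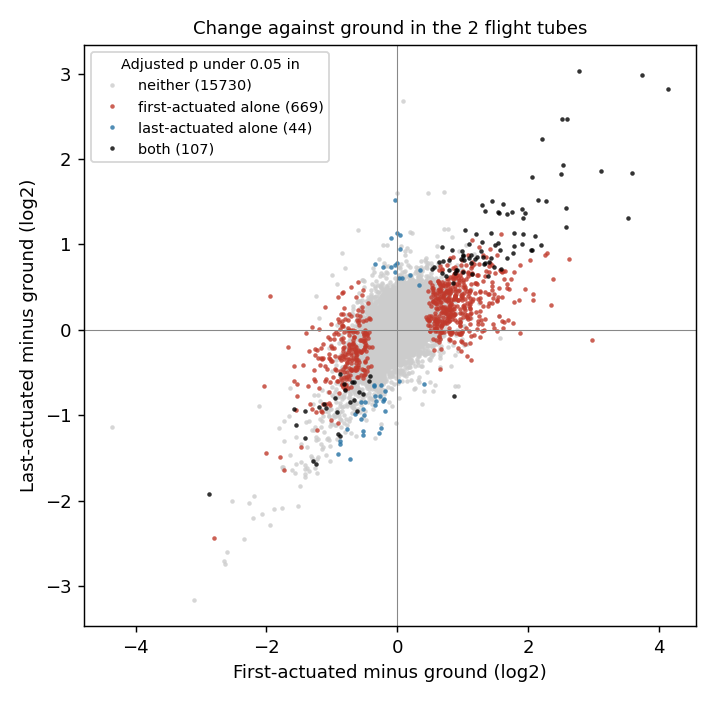
Log2 change against ground in first-actuated roots (horizontal axis) and in last-actuated roots (vertical axis), with 1 point per gene for the 16550 genes tested, coloured by the comparison in which the gene was called. Of the 107 genes called in both, 106 changed in the same direction in both and AT4G27657 in opposite directions.

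The third comparison set last-actuated against first-actuated roots, and so does not use the ground levels, although the ground arrays enter the estimate of spread. AT4G39675, a gene of the longer hypoxia list, stood at 4.46 ± 0.23 (SD, n = 3) in last-actuated and 2.12 ± 0.14 in first-actuated roots (limma, adjusted p = 1.30e-04), the latter below the median gene mean of 2.15. AT5G42200 (1.56 on the log2 scale) and AT4G27450 (1.00) of that list also rose, and in total 5 of its 24 measured members did (3 without first-actuated replicate 1 or 3 or last-actuated replicate 1 or 2). In the other direction, AT2G36690 fell from 5.66 ± 0.044 to 2.57 ± 0.13, 8.51-fold lower, against 2.68 ± 0.67 on the ground. STZ fell by 0.99 to 8.06 ± 0.12, against 8.10 ± 0.41 on the ground, and GH3.3 fell by 1.04. The longer hypoxia list as a whole did not pass (median 0.071, camera, adjusted p = 0.0953), but did without first-actuated replicate 2 (0.0456) and with genes above the median (median 0.40, 0.0400). The calls of STZ were lost without any 1 flight array (adjusted p = 0.0665 to 0.0976), and those of GH3.3 without any 1 array other than ground replicate 1 or 2 (0.0844 to 0.169). The touch list passed without last-actuated replicate 1 (adjusted p = 0.0213), with 0.0953 over all arrays.

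Cytosolic ribosomal protein transcripts were higher in last-actuated than in first-actuated roots. Of 129 measured members 107 had a positive log2 change and 16 rose, with a median of 0.25 (camera, adjusted p = 5.71e-15, and adjusted p = 0.218 with an estimated correlation). AT4G34670 rose from 6.65 ± 0.045 to 7.64 ± 0.095 and AT3G28900 from 4.34 ± 0.25 to 5.37 ± 0.12. The number that rose was 2, 3 and 5 without first-actuated replicates 1, 2 and 3, and 6, 5 and 7 without last-actuated replicates 1, 2 and 3. The 39 chloroplast photosynthesis genes had a median of -0.28 (camera, adjusted p = 1.79e-04, and adjusted p = 0.804 with an estimated correlation). Among them psaB fell by 0.90 and psbM rose by 0.67. The count that fell was 3 without ground replicate 1 or 2. The call of psaB was lost without any 1 flight array other than last-actuated replicate 3 (0.0702 to 0.0866), and that of psbM without any 1 flight array (0.0650 to 0.108). The 24 other chloroplast genes had a median of -0.24 (camera, adjusted p = 0.178, and 0.0208 without ground replicate 2), and limma called none of them, with 2 at an unadjusted p under 0.05. The fixed heat shock list had a median of -0.087 (camera, adjusted p = 0.557), and limma called none of its members over all genes, with 1 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. The longer list had a median of -0.082 (adjusted p = 0.113, and 0.0350 without last-actuated replicate 2), with 11 of 15 members negative. AT1G52560 was its 1 member called over all genes, and fell by 0.76. Adjusted over the list alone 3 were lower (1 without first-actuated replicate 2 or 3 or last-actuated replicate 1 or 3).

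In all, 371 genes differed between the flight tubes (limma, Benjamini-Hochberg adjusted p under 0.05), of which 163 rose and 208 fell from first- to last-actuated roots, and 113 changed by at least 1 on the log2 scale. The largest rises after AT4G39675 were those of PDF1.4, a plant defensin gene, from 6.40 ± 0.35 to 8.16 ± 0.24, AT5G42200, BGLU40, a beta-glucosidase gene (1.52), AT3G27030 (1.46) and AT5G02580 (from 1.43 ± 0.10, below the median gene mean of 2.15, to 2.82 ± 0.094). After AT2G36690, AT1G72760 fell by 2.22, AT1G14642 by 2.06, AT1G10040 by 1.91, AT5G13880 by 1.81 and AT1G73740 by 1.79. The root hair marker EXPA18 fell by 0.90, and 1 root hair marker rose and 1 fell adjusted over the list alone. Adjusted over the list alone, the counts up and down were 0 and 1 for touch and calcium signalling, 1 and 1 for hypoxia, 0 and 2 for auxin response and 1 and 1 for the abscisic acid, cold and drought list. Over all genes these were 0 and 1, 1 and 0, 0 and 1, and 0 and 0. Limma called none in the cell wall, circadian clock and reference gene lists, over all genes or adjusted over the list alone, with 1 member of each at an unadjusted p under 0.05. Of the 499 genes that rose in first-actuated against ground roots, 169 were lower in last- than in first-actuated roots, and of the 277 that fell, 77 were higher. These comparisons share the first-actuated arrays, so their chance values are not independent. Genes picked for extreme first-actuated levels lean toward such a return by selection alone, and how many would do so was not simulated. The comparison called 118, 133 and 100 genes without first-actuated replicates 1, 2 and 3, and 179, 178 and 176 without last-actuated replicates 1, 2 and 3. With a weight for each array it called 597. The call of PDF1.4 was lost without first-actuated replicate 3 (adjusted p = 0.0509). That of BGLU40 was lost without ground replicate 3, any 1 first-actuated array, or last-actuated replicate 1 or 3 (0.0539 to 0.114), and that of EXPA18 without any 1 array other than ground replicate 2 (0.0515 to 0.154).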

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

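The tests of heat shock, chloroplast-encoded and ribosomal protein genes below were chosen only after their results were seen, while the tests of other groupings of the arrays were planned.

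Heat shock transcripts were higher in both flight tubes than on the ground, with medians of 2.33 and 1.99 over the 4 fixed genes. No ground array carries this by itself, since the lowest median over the fits without 1 ground array was 1.88. A trend with brightness left by the normalization is argued against, since both medians lay at percentile 100 of 10000 random lists matched on mean level, whose central ranges were -0.46 to 0.69 and -0.43 to 0.40. What stays open is the flight itself, other conditions of the tubes such as temperature, and the handling of single tubes, which cannot be told apart because each condition had 1 tube. A response of roots to the flight conditions may account for it, and this was not tested.

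Chloroplast-encoded transcripts were lower in both flight tubes, with medians of -0.88 and -1.11 over 63 genes, but the calls of their 2 lists were lost with an estimated correlation (adjusted p = 0.421 for each in first-actuated roots, and adjusted p = 0.189 and 0.279 in last-actuated roots), and 6 of 39 and 1 of 24 members fell in first-actuated and 11 and 2 in last-actuated roots (29, 23, 32 and 22 without ground replicate 2, and at most 1, 0, 4 and 0 without any other array). A brightness trend is argued against, since both medians lay at percentile 0 of the random lists. Shoot tissue left on the ground roots may be the cause and stays open, since 15 measured of 64 nuclear photosynthesis genes, listed after RCA and LHCB4.1 had been seen, had medians of -0.53 and -0.60 (-0.32 and -0.24 without ground replicate 1, and -0.84 in first-actuated roots without ground replicate 2). The gap to the chloroplast-encoded genes was 0.353 in first-actuated and 0.512 in last-actuated roots, against SDs of the nuclear changes of 0.44 and 0.49. It was 0.153 against an SD of 0.45 in first-actuated roots without ground replicate 3. In last-actuated roots without ground replicate 2 it was 0.807 against 0.60. The nuclear genes had a median ground level of 3.75, against 8.43 for the chloroplast-encoded ones, so the sizes of their changes may not be comparable. Of the 15 nuclear genes, 13 were negative in each tube. PSBY (-0.83, first-actuated), LHB1B2 (-0.91 and -1.22) and PSAE-1 (-1.30 and -1.53) fell, while RCA and LHCB4.1 were not called. Spread among the ground arrays also stays open, since ground replicate 2 lay 0.141 above the highest flight array, and a biological difference between the tubes was not tested.

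Cytosolic ribosomal protein transcripts were lower in first-actuated than in ground roots, with a median of -0.33. The lowest last-actuated array lay 0.153 above the highest first-actuated array in median deviation. Ground levels enter that gap, since each gene's deviation was taken from its mean over all arrays. They do not enter the median log2 change of 0.25 from first- to last-actuated roots. There 107 of 129 genes were positive and 22 negative. That change argues against spread among the ground arrays as the sole cause, though the list's call was lost with an estimated correlation (camera, adjusted p = 0.218). The rule for the gap was also laxer than for chloroplast-encoded transcripts. Here any positive gap sufficed, there a larger one was asked for, and both rules were set after the values were seen. A brightness trend is argued against, since the median lay at percentile 0 of the random lists. The handling of the first-actuated tube and the flight phase cannot be told apart, since 1 tube stood for each, and either may be the cause of the gap of 0.153.

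The cytosolic ribosomal protein list differed between the flight tubes (camera, adjusted p = 5.71e-15, and adjusted p = 0.218 with an estimated correlation), as did the chloroplast photosynthesis list (1.79e-04, and adjusted p = 0.804 with an estimated correlation). AT4G27657 was higher in first-actuated roots (4.70 ± 0.15) and lower in last-actuated roots (3.06 ± 0.13) than on the ground (3.83 ± 0.25), and the flight tubes differed by -1.64 on the log2 scale (limma, adjusted p = 0.00143). Its call in last-actuated against ground roots was lost without any 1 array other than ground replicate 1 (0.0548 to 0.159). A separate fit took in all 38408 probe sets and adjusted over all of them, so its counts are not comparable with those of the named genes. Of the 21686 without a single gene name, 773 differed between first-actuated and ground roots (459 higher and 314 lower). Between last-actuated and ground roots 145 differed (69 and 76), and between the flight tubes 365 (148 and 217).

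With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real splits, each the 1 split of its 10 with as many calls, gave 776, 151 and 371 genes, and the highest of the other splits gave 0, 0 and 1. For the F test, 1 of 100 splits drawn from the 280 of the 9 arrays, the real one, gave as many genes as 737. The highest other gave 346, so chance in how the arrays fell into groups is argued against for that count. Since the 3 arrays of a group came from 1 tube, this shows only that arrays of a tube resemble each other, whatever sets the tubes apart.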

How the results depend on the processing

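The alternatives here were all planned, and only the counts of list members without single arrays were chosen after their results were seen. No gene or list result that was called in the main fit or in an alternative changed direction there. Among results called in neither, up to 3 gene and 8 list results changed sign in a single alternative. The balance of rises and falls also moved. Without ground replicate 2, last-actuated against ground gave 240 rises and 268 falls, against 96 and 55 over all arrays. Without last-actuated replicate 1, last- against first-actuated gave 94 and 85, against 163 and 208. Both normalizations kept the side of the threshold for 125 (quantile) and 121 (cyclic loess) of 129 gene results and for all 81 list results, and the calls of first-actuated against ground, last-actuated against ground and last- against first-actuated roots numbered 815, 192 and 404, and 857, 181 and 454. With genes above the median alone, last-actuated against ground gave 255 genes and the overlap of the flight comparisons 172. This filter changed both the number of genes tested and the moderation, and which of them moved the counts was not tested. With array weights, last- against first-actuated gave 597, and the cause was not tested. With all probe sets tested, the 3 comparisons gave 1306, 228 and 596 and the F test 1219, but kept 528 of 776, 82 of 151 and 231 of 371 calls, and 28 of 129 gene results were weaker. At adjusted p under 0.01 they gave 327, 43 and 94, the F test 259 and the overlap 37, and with a log2 change of at least 1 they gave 281, 59 and 113, 315 and 42, as stricter thresholds do. With the 2 compared groups alone, first-actuated against ground gave 419 and last-actuated against ground 28 (27 higher and 1 lower). Last- against first-actuated gave 414, and the overlap was 26. The 3 comparisons kept 401, 27 and 298 calls, and the cause was not tested. With genes above the median, the cytochrome P450 list in first-actuated against ground roots also passed (camera, adjusted p = 0.0245, and 0.0245 to 0.609 over its alternatives). Of 13 list calls, 5 held with an estimated correlation and 8 with fry. Without each array in turn, the counts ran from 384 to 1253, from 53 to 508 and from 100 to 495, for the F test from 327 to 1216 and for the overlap from 40 to 416. The highest counts came without ground replicate 2, apart from last- against first-actuated, where it was ground replicate 1. Of 41, 23 and 27 named called genes, 26, 8 and 16 were called in all 9 of these fits. Replicate numbers do not pair the samples, with correlations of deviations between arrays of a number from -0.106 to 0.0698. With a replicate block, the counts were 700, 109 and 303, 640 for the F test, 86 for the overlap and 13 for the lists. Signal over background limits genes near the floor: of 4138 genes at or below a mean of 1.41, 2, 0 and 1 were called by limma.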

Other observations

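The tests of equal values were chosen only after an SD of 0 was seen, while the list tests here were written before any test.

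Single members of enzyme families of the cell wall and of secondary metabolism were called. Of 56 measured class III peroxidases, which act on the cell wall and on peroxide, 4 rose and 3 fell in first-actuated against ground roots (1 and 2 without ground replicate 1 or first-actuated replicate 1 or 3), and AT1G49570 fell from 5.14 ± 0.096 to 3.75 ± 0.011 (limma, adjusted p = 6.18e-04). It was higher again by 1.36 in last- than in first-actuated roots. Of 51 measured UGT glycosyltransferases 4 rose and 1 fell in first-actuated roots (camera, adjusted p = 0.394), and UGT73B5 and UGT73B2 rose by 0.88 and 0.58. These counts were 2 up without ground replicate 1 or first-actuated replicate 2 or 3, 2 down without ground replicate 2 and 0 down without first-actuated replicate 2 or 3. UGT73B4 rose by 0.74 in last-actuated roots, a call lost without any 1 array other than ground replicate 2 or 3 (adjusted p = 0.0629 to 0.117). Of 22 measured beta-glucosidases, out of 40 listed, 1 rose and 1 fell in first-actuated roots (camera, adjusted p = 0.304). BGLU27 rose from 1.44 ± 0.26 to 3.13 ± 0.48 and fell from there to 1.55 ± 0.13 in last-actuated roots. BGLU42 fell by 0.61, a call lost without any 1 array other than ground replicate 3 (adjusted p = 0.0543 to 0.169), and 2 members fell without ground replicate 2. Of 25 measured cytochrome P450 genes, out of 236 listed, 3 rose and 0 fell in first-actuated roots (camera, adjusted p = 0.304), with 1 rise without first-actuated replicate 1. CYP71B34 rose from 1.83 ± 0.060 to 2.52 ± 0.14 in first-actuated and 2.80 ± 0.12 in last-actuated roots. The lowest levels of BGLU27 and CYP71B34 lay below the median gene mean of 2.15 and are not shown to be above background. Of 22 measured expansins, out of 34 listed, 1 rose and 1 fell in first-actuated roots (camera, adjusted p = 0.664). EXLA1, an expansin-like gene, fell by 0.76, and 2 members fell without ground replicate 2. The 1 rise, that of EXPA18, was lost without ground replicate 1 or 3 or first-actuated replicate 1 or 3 (adjusted p = 0.0690 to 0.0861). The peroxidase list did not pass in any comparison (camera, adjusted p = 0.733, 0.368 and 0.223).

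Of the lists with 1 or 2 measured members, HYH was the 1 gene called. EIN3, a transcription factor of ethylene signalling, had log2 changes of -0.10 and -0.060 against ground in first- and last-actuated roots, PDF1.2, a defensin gene of pathogen defence, 0.25 and 0.28, BHLH101, of iron deficiency, 0.016 and 0.078, and AT2G21640, an oxidative stress marker, 0.57 and 0.14. The levels of PDF1.2 (0.79 ± 0.14 on the ground) and BHLH101 (1.74 ± 0.012) lay below that median. By limma 0 of these were called, with 1 oxidative stress gene at an unadjusted p under 0.05 in first-actuated roots. Of the called genes, 0, 4 and 1 in the 3 comparisons had values identical in every deposited digit on all arrays of a compared group, among them AT5G19890, a peroxidase gene at 2.95 with an SD of 0 in last-actuated roots. Its call in last-actuated against ground roots was lost without any 1 array other than ground replicate 2 (adjusted p = 0.0546 to 0.140).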
